A study of Mus musculus with 2 samples.

How the data were processed

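H3K27ac chromatin immunoprecipitation sequencing (ChIP-seq) was measured in 2 libraries of activated regulatory T cells from an adult male mouse of 4 months, per the labels. The labels give the 2 libraries as technical replicates 1 and 2 of 1 biological replicate with the same biosample and donor, so both belong to 1 group and the series holds 1 biological sample. The labels name no input, control or second condition among these libraries.

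Each deposited table holds 1 whole-number count for each of 33643 numbered regions. Per the file descriptions deposited beside the tables, the counts were derived by the authors from each library's alignments to mm10 and from 1 reference file shared by both libraries. The aligner, the counting tool, any filter on reads, any removal of duplicate reads and the way the regions were chosen are not given in the sources used here. The region numbers run from 1 in both tables and are identical in the same order. The tables pair the numbers with no coordinates or gene names, and region coordinates were not used here, so regions are named by number and the reference annotation was not used. The 13 gene lists fixed in advance (181 genes), the genomic distribution of the regions and the other results that need positions were therefore not computed.

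The counts were used as deposited, with no normalization and no filter. The total over the regions was 551545 counts in replicate 1 and 630881 in replicate 2. These totals cover the regions only and are not the sequencing depth of the libraries, which is not given in the sources used here. Log2 values were taken after adding a pseudocount of 1, and the log2 ratio of replicate 2 to replicate 1 was centred on its median over regions. Because fold changes include that pseudocount, those of regions with few counts are understated.

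Agreement between the libraries was measured with Pearson's r of the log2 counts, Spearman's rho, the SD of the centred log2 ratio and the percentage of regions within 2-fold, all across regions, which are not independent replicates. To show what counting noise alone would give, each region's summed count was divided at random between the libraries in proportion to the library totals, 100 times for the agreement measures and 1000 times for the variance ratio. The variance ratio is the mean over regions of the squared difference between the replicate 2 count and its expected share of the summed count, divided by the binomial variance of that share. It is 1 for pure counting noise, above 1 where libraries differ more and below 1 where they differ less. Each region was tested with an exact two-sided binomial test with the library totals as offsets, with Benjamini-Hochberg adjustment at 0.05 over the 33577 regions with a count above 0. This test compares 2 libraries and covers counting error only. With 1 group and 1 biological sample, no model with replicate variance could be fitted.

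The per-region test and the variance ratio were tested on simulated data drawn from the regions' means and the library totals. With 100 regions changed 2-fold and 100 changed 4-fold between the simulated libraries, all at or above the median count, 14 of the former and 72 of the latter were called, beside 2 of the 33443 unchanged regions. Intervals at 95% are exact Poisson intervals for counts and exact Clopper-Pearson intervals for shares, and cover counting error only. A region with no count in a library is given the limit that 3 counts would set.

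The rule for named features was fixed before the data were examined. It takes the 10 regions with the highest mean count and the 3 with the largest centred log2 ratio in each direction among regions at or above the median. Because these are bare numbers, at most 2 are printed for each part of the rule and the rest are summarised. Alternatives fixed in advance were a pseudocount of 0.1, upper-quartile scaling, a threshold of 0.01 and a restriction to regions at or above the median mean count. The order of the regions was examined by the largest step in mean log2 count and by correlations between region numbers, against 1000 permutations of the order. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.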

Results

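H3K27ac, an acetylated lysine of histone H3 that marks active promoters and enhancers, was profiled by ChIP-seq in activated regulatory T cells, the Foxp3-expressing CD4 T cells that restrain immune responses. The cells came from a mouse line that carries a tamoxifen-inducible Cre recombinase at Foxp3 and a Cre-dependent YFP reporter at Rosa26, which together allow Foxp3-expressing cells to be marked. Both libraries were technical replicates of 1 biological sample, so no value below carries a biological error. The 33643 counted regions were covered by 551545 counts in replicate 1 and 630881 counts in replicate 2, a ratio of 1.14. The deposited regions carry numbers only, and they are named by number here.

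H3K27ac counts were unevenly spread over the regions. The median region held 9 counts in replicate 1 (95% exact Poisson interval 4.12 to 17.1) and 10 counts in replicate 2 (interval 4.80 to 18.4). These intervals are for a single region with that count, not for the median over regions. Between the lower and upper quartile, regions ranged from 4 to 21 counts in replicate 1 and from 5 to 24 in replicate 2. The variance of the summed counts over regions was 48.4 times their mean, where equal regions with counting noise would give 1. The 3364 regions with the most counts, 10% of all regions, held 38.2% of the summed counts (95% exact Clopper-Pearson interval 38.1 to 38.3). When the 3364 regions were chosen in replicate 1 and measured in replicate 2, the share was 37.5% (interval 37.4 to 37.6). Chosen and measured in replicate 2 it was 38.4%, so selecting and measuring in the same library raised the value by little. The intervals take the chosen regions as fixed and do not cover their selection. At the other end, the 17436 regions with a summed count under 20 made up 51.8% of the regions and held 14.5% of the counts.

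A pair of regions stood above the rest in both libraries. Region 6635 held 431 counts in replicate 1 and 455 in replicate 2, and its sum of 886 counts was 49.2 times the median region. Region 18076 followed with 338 and 365 counts, and the next region had a summed count of 473. The 10 regions with the most counts had summed counts from 346 to 886. Of these 10 regions, 9 were among the highest 10 of replicate 1 and 9 among the highest 10 of replicate 2. Together they held 0.403% of all counts, so no small set of regions took most of the counts. Region widths were not used and the labels name no input, so a high count need not mean more acetylation per base.

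The counts also followed the order in which the regions are numbered. The largest step in mean log2 count lay after region 20364. The regions up to it had a median of 31 summed counts and the 13279 regions after it a median of 10, and the ratio of their mean summed counts was 3.02. Placed in each library alone, the step lay after region 20365 in replicate 1, with a ratio of mean counts of 3.00, and after region 20427 in replicate 2, with a ratio of 3.04. None of 1000 permutations of the order gave a step as large (permutation p = 0.001, the smallest they can give). The test of the step was chosen after the counts had been seen.

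**Figure D1:**
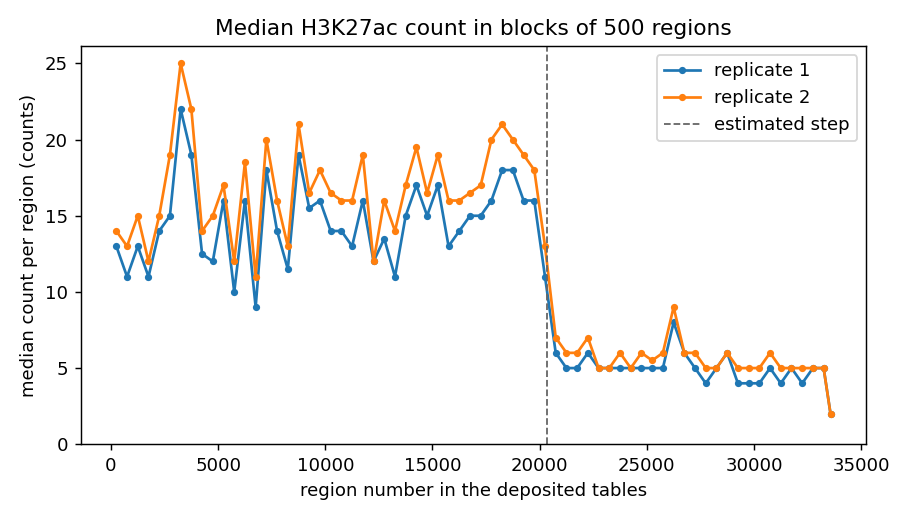
Median count per region (vertical axis, counts) in successive blocks of 500 regions by region number (horizontal axis), for replicate 1 and replicate 2, with the last block shorter. The dashed line is the estimated step, across which the block medians fall from between 9 and 25 to between 2 and 9, apart from the block that holds the step.

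Few regions had no count. In replicate 1, 664 regions (1.97%) had no count, and in replicate 2, 469 regions (1.39%) had none. Only 66 regions had no count in either library, which allows up to 3 counts each in the summed total of 1182426. Regions with no count in one library had at most 12 counts in replicate 2 or 8 counts in replicate 1.

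The design compares the 2 technical replicates, which asks how precisely the level of H3K27ac at each region was measured. Regions ranked alike in both. Across regions, Pearson's r of the log2 counts was 0.887 and Spearman's rho was 0.892. Random divisions of the summed counts gave a mean r of 0.886 (range 0.883 to 0.890) and a mean rho of 0.890, with all of them below the observed rho. The centred log2 ratio of replicate 2 to replicate 1 had an SD of 0.69 over regions, against a mean of 0.69 in random divisions, and 87.2% of regions lay within 2-fold. Of the 3364 regions with the most counts in each library, 2885 (85.8%) were shared, which is above the 2800 to 2859 of random divisions. Independent lists would share 336.

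**Figure D2:**
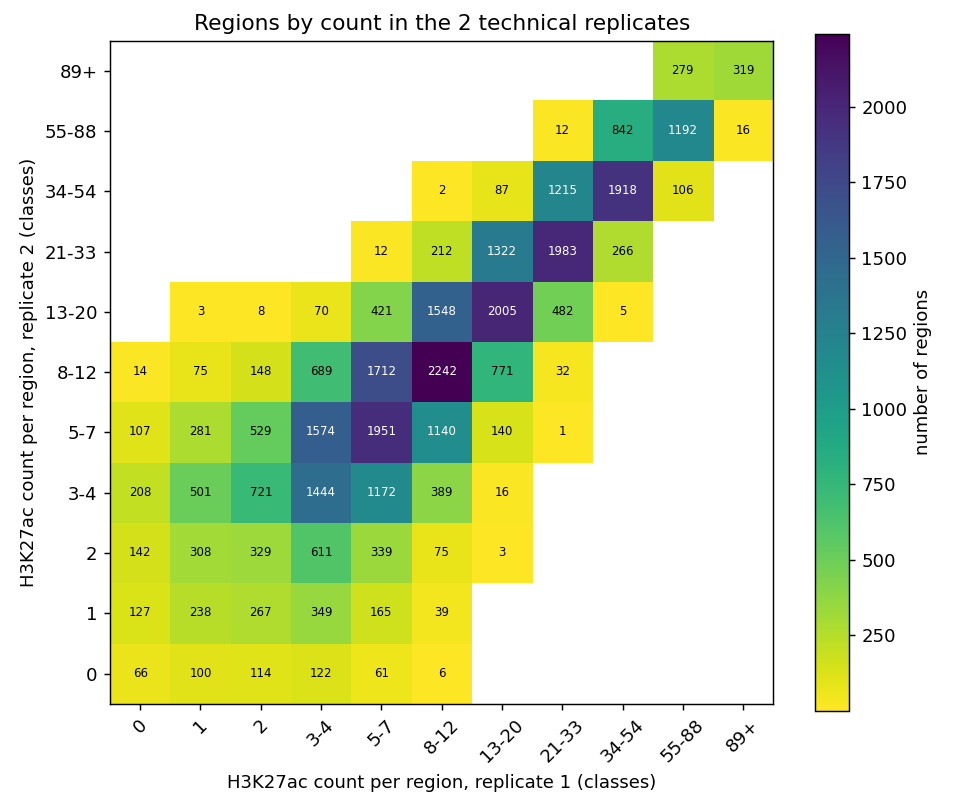
Number of regions by count in replicate 1 (horizontal axis, counts per region in classes) and replicate 2 (vertical axis, same classes), with the number written in each cell. Regions lie along the diagonal, with 40.7% in the same class and 84.0% in the same or the next class, and 319 regions have 89 or more counts in both libraries.

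No region passed the test for a difference between the libraries. The exact binomial test with Benjamini-Hochberg adjustment called 0 of 33577 regions, with a lowest adjusted p of 1, and the mid-p form of the test also called 0. At an unadjusted p under 0.05 there were 1063 regions, fewer than the 1123 to 1294 in 100 random divisions of the same counts. Among regions at or above the median, region 11340 had 17 counts in replicate 1 and 3 in replicate 2, and region 27790 had 16 and 3. In the other direction, region 25296 had 2 and 17 counts and region 33125 had 2 and 16. Their centred log2 ratios of -2.35, -2.27, 2.40 and 2.32 each had an adjusted p of 1 in the exact test. In simulated libraries of this depth, with all changed regions at or above the median count, 72 of 100 changed 4-fold and 14 of 100 changed 2-fold were called. Differences of 2-fold at single regions were therefore mostly not detectable at this depth. All these regions were changed at once and none lay below the median. The simulation therefore does not show how often a lone change, or a 4-fold change in a region with fewer counts, would be called. It also drew full counting noise, while the real libraries differed by less than that in regions with many counts.

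The 2 libraries differed by less than the sampling noise and were counted as 1 sample. Over all regions the variance ratio was 0.950 ± 0.0070 (SE over regions), below the lowest of 1000 random divisions, 0.979. Regions with summed counts of 5 to 9 had a ratio of 1.02 ± 0.017, within the random divisions. The ratio was 0.911 ± 0.017 for regions with 40 to 79 counts, 0.800 ± 0.019 for those with 80 to 159 counts and 0.747 ± 0.040 for those with 160 or more. Each of these 3 values lay below all 1000 random divisions of its class.

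**Figure D3:**
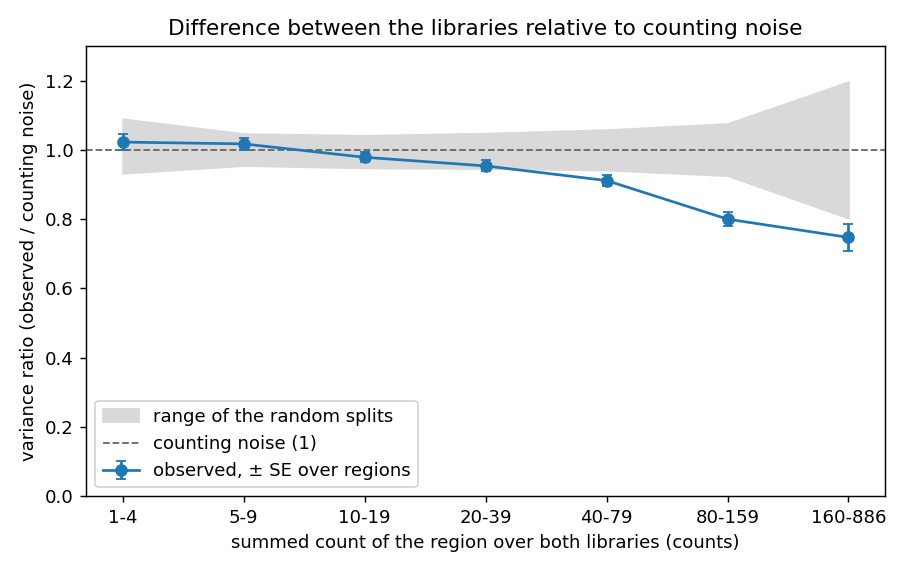
Variance ratio of the libraries (vertical axis, 1 is counting noise) by summed count of the region (horizontal axis, counts over both libraries). Points are observed values with the SE over regions, and the band is the range of 1000 random divisions. The ratio lies near 1 for regions with few counts and reaches 0.747 for regions with 160 to 886 counts.

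The share of counts from replicate 2 varied slightly between classes of summed count, with no steady order. Replicate 2 held 1.12 times the counts of replicate 1 in regions with a summed count under 20 and 1.15 times in regions with 20 or more. This share differed over the 7 classes in a chi-square test (29.6, permutation p = 0.001 from 1000 random divisions, the smallest they can give), which was not among the tests fixed in advance. The share ranged from 52.8% (95% exact Clopper-Pearson interval 52.3 to 53.2) at 5 to 9 counts to 53.6% (interval 53.4 to 53.8) at 40 to 79 counts, apart from the class of 1 to 4 counts at 54.0% (interval 52.8 to 55.1). It was 53.4% both at 80 to 159 counts and at 160 or more, as over all regions.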

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

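All 5 settings of the per-region test called 0 regions: library totals, upper-quartile scaling, a threshold of 0.01, regions at or above the median mean count, and the mid-p form, which was added after seeing the data. The lowest adjusted p over these was 0.963, with the mid-p form. Agreement between the libraries depended on how regions with few counts were treated. With a pseudocount of 0.1, Pearson's r was 0.804, the SD of the centred log2 ratio 1.11 and the share of regions within 2-fold 81.1%. With regions at or above the median mean count only, these values were 0.897, 0.43 and 96.7%, while Spearman's rho was 0.890. The variance ratio and its alternatives were chosen after seeing the data: it was 0.901 for regions at or above the median mean count, and stayed within 0.949 to 0.950 with upper-quartile scaling, with a replicate 2 share set per class of summed count, or without the 10 regions with the most counts. The share of counts in the 10% of regions with the most was 38.4% in each library alone. Alternatives that need region positions, widths or scores (overlap rules, windows around genes, promoter definitions, leaving out a replicate in those results) and those for curves were not run. Depth limits what single regions can show: the median region's 9 counts in replicate 1 have an interval of 4.12 to 17.1.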

Other observations

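The tests in this part were chosen after the counts had been seen, and the predictions for 2 of them (the variance ratio in the later part of the numbering and the correlation of successive regions) were written before those values were seen. The H3K27ac count per region changed with the region number. Regions 1 to 20364 had a mean summed count of 47.7 and held 82.2% of the counts, while the 13279 regions after them had a mean of 15.8. Regions with a summed count of 80 or more numbered 3980 in the earlier part and 257 in the later part. Within the later part, regions 25939 to 26368 formed a stretch with more counts per region: their mean count was 2.44 times that of the rest of the part in replicate 1 and 2.40 times in replicate 2. The stretch was chosen from windows of 50 to 2000 regions for its excess in the summed counts of both libraries. These folds therefore include that selection, and neither library gives independent support. The statistic of that stretch was 18.9, against at most 5.13 in 100 permutations of the order.

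The first pattern is this step. Nearly the same position was found in each library, at region 20365 in replicate 1 and region 20427 in replicate 2, and the mean count fell by a factor of 3.00 in replicate 1 and 3.04 in replicate 2. A fault of one library is argued against by the smaller of these factors, 3.00. An arbitrary order of the regions is argued against by 0 of 1000 permutations with a step as large. Whether the later regions are narrower, of another class or lower in acetylation per base was not tested, since region widths and positions were not used here, and no biological explanation was tested within 1 group.

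The second pattern is a weak correlation between the counts of regions with successive numbers. Within the earlier part the correlation of their log2 summed counts was 0.083, and within the later part it was 0.14, both beyond 1000 permutations (permutation p = 0.001, the smallest they can give). At a distance of 100 numbers the correlation was 0.0076 in the earlier part (permutation p = 0.297) and 0.033 in the later part, where it was still beyond the permutations (permutation p = 0.001). The stretch with more counts described above lies in the later part, and how much it adds to the correlations there was not tested. These values are consistent with a numbering that follows some property shared by neighbours, and genome position is a candidate explanation that the tables alone cannot check further.

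The third pattern is the difference between libraries that was smaller than counting noise. It is defined by the random divisions, of which 0 of 1000 gave a ratio as low, so these are no separate test of counting noise. Reads or molecules present in both libraries in one proportion for every region were predicted to lower the ratio by a similar amount at low and high counts. This is approximate, since regions with the fewest counts leave no room for a shared read. The ratio under a summed count of 10, however, exceeded that at 80 or more by 0.227 ± 0.022 (SE), and was 1.02 ± 0.014. A limit on the counts a region can gain, as removal of duplicate reads sets, would lower the ratio mainly in regions with many counts. The prediction written beforehand was a variance ratio below 1 at 80 or more counts in both parts, and near 1 under 20. In the earlier part the variance ratio was 0.787 ± 0.018 at 80 or more counts and 0.998 ± 0.016 under 20. In the later part it was 0.861 ± 0.080 in 257 regions with 80 or more and 0.999 ± 0.013 under 20. Both parts went with the prediction, though the later value at 80 or more has a wide SE. Such a limit alone would also take more from the larger library, and so lower the share of replicate 2 in regions with many counts. In the earlier part, replicate 2 held 1.115 times the counts of replicate 1 under 20, 1.151 times at 20 to 79 and 1.146 times at 80 or more. The later part had 1.125, 1.150 and 1.127 times in the same classes. These values rose from the lowest to the middle class and fell from there to the highest. With no steady order over the classes, they cannot decide for or against the limit. The limit is left open, since the few later regions with many counts leave the size of the fall there uncertain. The variance ratio of the later part was 0.995 ± 0.027 in 2571 regions with 20 to 79 counts, against 0.918 ± 0.013 in the earlier part. The mean summed counts of these regions were unlike, at 33.4 in the later part and 42.5 in the earlier. At equal summed counts of 20 to 79 the later part exceeded the earlier by 0.059 ± 0.031 (SE), and sharing that grows with the count of a region was not tested.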
